A study of Mus musculus with 45 samples.

How the data were processed

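Gene expression was measured by RNA sequencing in cultured mouse tumour cells of 2 lines, CT26 (colon carcinoma) and Hepa1-6 (a liver line). In the drug experiment, cells were exposed for 48 hours to DMSO, the solvent control, or to a compound that the labels name only as stk. In the knockdown experiment, lines carrying a short hairpin RNA against Soat1, the gene of sterol O-acyltransferase 1, or a control hairpin were collected 24 hours after seeding. The control hairpins are against luciferase (shLucif) in both lines and a scrambled hairpin in Hepa1-6. The labels give 1 batch date per experiment, so no group is split between dates. Responses were compared between the experiments only through fold changes made inside each of them. Levels were set side by side across the experiments only to ask what the Hepa1-6 shLucif libraries hold.

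The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), made by the authors as 1 table per experiment with 55335 genes each. Per the labels, RNA was total RNA, libraries were sequenced in pairs of reads and reads were trimmed with Skewer. The submitters' processing notes list the genome build GRCm38 and the tools HISAT2, STAR, DESeq2 and edgeR. Which of them made the FPKM, and their versions, are not given in the sources used here. FPKM carry no read totals, so the sequencing depth of each library is unknown and no counting interval could be computed. The lowest FPKM steps of each library give a relative depth, estimated from values under 0.05 FPKM with a tolerance of 0.01 on the log2 scale. It lay between 0.895 and 1.122 in the drug table and between 0.885 and 1.304 in the knockdown table.

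Of the 45 labelled samples, 30 have a column whose name matches them, 12 in the drug table and 18 in the knockdown table, and these make 10 groups of 3 libraries. The labels list 6 stk samples per line, of which 3 have a matching column. A further 21 columns match no label (12 in the drug table and 9 in the knockdown table) and were not used here, and no sample was assigned by its values. The names of the distributed tables are swapped between the experiments, so each table was assigned by its column names. No column matches the 3 Soat1 hairpins of Hepa1-6, so those comparisons, and the test of whether the knockdown acts differently in the 2 lines, were not analysed here. Each column of hairpin sh1 ends in a pair of numbers that does not single out 1 labelled sample, so these columns were used as a group and left out of the replicate block by choice.

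Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1) of the values as deposited. The pseudocount of 1 shrinks fold changes of genes with low FPKM. Each line of each experiment had its own model with a mean per group, and all of its contrasts came from that model. Genes with at least 1 FPKM in at least 3 libraries of the model were tested, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were stk against DMSO in each line, each Soat1 hairpin and the mean of the 3 hairpins against shLucif in CT26, scramble against shLucif in Hepa1-6, and the difference between the lines in the response to stk. Calls shared by 3 hairpins with 1 control group were compared with 100 simulated sets of unchanged groups that share their control. Overlaps between comparisons used one-sided Fisher exact tests, adjusted over 8 tests, and over 6 where the overlap of the lines was repeated under other settings. With 3 libraries against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so no such test was used.

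The comparisons, the threshold, the gene lists and the alternatives were fixed before the data were examined. The 32 lists hold 628 entries, of which 627 matched a gene of the tables (H2-L did not). They cover cholesterol biosynthesis, sterol uptake and SREBP2 regulation, LXR targets, fatty acid synthesis, sterol esterification and lipid droplets, oxysterol and steroid enzymes, oxysterol receptors and binding proteins, and stem cell markers. They also cover MHC class I antigen presentation, immune checkpoint ligands, chemokines and cytokines, interferon-stimulated genes, NF-kB targets, ATF4 targets, ER chaperones, p53 targets, NRF2 targets, xenobiotic metabolism, glycolysis and hypoxia, Wnt targets and immediate early genes. The remaining lists are DNA replication, mitosis, replication-dependent histones, mitochondrially encoded mRNAs, lysosome, mesenchymal and matrix genes, and markers of hepatocytes, intestinal epithelium, leukocytes, fibroblasts and endothelium. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, adjusted over lists and comparisons. List tests for single hairpins, for sh3 against the mean of sh1 and sh2 and for scramble form a second family that was added after the data were seen.

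Genes named in the results were chosen by a fixed rule. Soat1, Soat2, Gpr132 and Cyp11a1 are named in every comparison. For each main comparison, the rule takes up to 10 genes each way with the largest fold change among called genes with a group mean of at least 5 FPKM, libraries that do not overlap between the groups and a symbol that is not a predicted name. For the mean of the hairpins, it also asks for a call in the same direction with each hairpin. For other comparisons it takes 3 genes each way, and from each list up to 4 members by moderated t. Other genes are named as chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38, which holds 99.67% of the gene identifiers, and 3225 genes of the tables carry no symbol.

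The method was tested on simulated data with the gene means and spreads of each comparison and genes that vary independently, with fold changes of 1.2, 1.5 and 2 added to 67, 67 and 66 genes and a shift added to 1 of 21 random lists. Between 5 and 10 unchanged genes were called per comparison, the shifted list was called in each and 0 unshifted lists were. The comparisons with shLucif called 37.8% to 68.2% of the genes tested, a far larger share than was changed in the simulation. The adjustment is less strict where more genes change, so the simulated detection rates may not hold for those comparisons. The alternatives, whose effect the closing section gives, were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, size factors, the replicate number as a block, 1 model for a whole table, an estimated correlation for the lists and the omission of each library. Alternatives added after the data were seen were protein-coding genes only, removal of the trend with transcript length, other weightings of the hairpins, and the contrasts of sh2 with sh1 and of sh3 with the mean of sh1 and sh2. Every other grouping of the libraries, or 100 drawn with the seed 20240514 where there are more, was run through the same test. Whether replicates of a group are separate cultures or repeated libraries is not stated, so errors and p-values measure only the spread between these libraries.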

Results

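The data are FPKM values of 55335 genes in 30 RNA libraries from 2 mouse tumour lines, in 10 groups of 3. The drug experiment holds CT26 colon carcinoma cells and Hepa1-6 liver cells, each with DMSO and with the compound named stk. The knockdown experiment holds CT26 with the control hairpin shLucif or with 1 of 3 hairpins against Soat1 (sh1, sh2 and sh3), and Hepa1-6 with shLucif or a scrambled hairpin. FPKM sums ran from 314827 to 335066.6 per library in the drug table and from 320249.2 to 335812.8 in the knockdown table. Between 11228 and 11407 genes reached 1 FPKM per library in the drug table, and between 11159 and 11555 in the knockdown table. Read totals are unknown. Values are group means in FPKM ± SD (n = 3 libraries), fold changes are log2 of FPKM + 1 with their standard error (SE), and adjusted p-values are from limma with the Benjamini-Hochberg method.

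The title of the study names SOAT1, an enzyme that esterifies cholesterol, as a checkpoint of cancer stem cells that acts through a hydroxycholesterol and its receptor GPR132. The level of the targeted gene therefore comes first. In CT26, Soat1 (ENSMUSG00000026600, GRCm38 chromosome 1, 156424525 to 156474331) stood at 19.9 ± 0.254 FPKM with shLucif, 3.27 ± 0.035 with sh1, 3.47 ± 0.074 with sh2 and 2.59 ± 0.104 with sh3. These levels are 16.4%, 17.4% and 13% of the control. Soat1 fell with the mean of the 3 hairpins by 2.35 on the log2 scale (SE 0.0337, limma adjusted p = 1.12e-11). Soat2, the second enzyme of the family, was at 59.9 ± 1.71 FPKM with shLucif and 54.3 ± 5.52 over the hairpins, a difference that did not pass the test (log2 fold change -0.15, adjusted p = 0.0754). With sh2 alone it fell to 49.7 ± 2.13 FPKM (-0.27, adjusted p = 0.0156), and with sh1 (adjusted p = 0.168) and sh3 (0.754) it did not pass. In the drug experiment, Soat1 in CT26 was 12.3 ± 0.214 FPKM with DMSO and 12.8 ± 0.73 with stk (log2 fold change 0.05, adjusted p = 0.706), and Soat2 was 13.3 ± 0.605 and 14.9 ± 0.501 (0.15, adjusted p = 0.252). Unmodified Hepa1-6 cells held little of either mRNA. Soat1 stood at 0.139 ± 0.016 FPKM with DMSO and 0.081 ± 0.039 with stk, and Soat2 at 0.199 and 0.377, all below the minimum for testing. Gpr132 and Cyp11a1, whose product makes steroid precursors from cholesterol, were below 1 FPKM in every group, with highest group means of 0.753 and 0.642 in Hepa1-6 scramble, and were not tested.

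**Figure D1:**
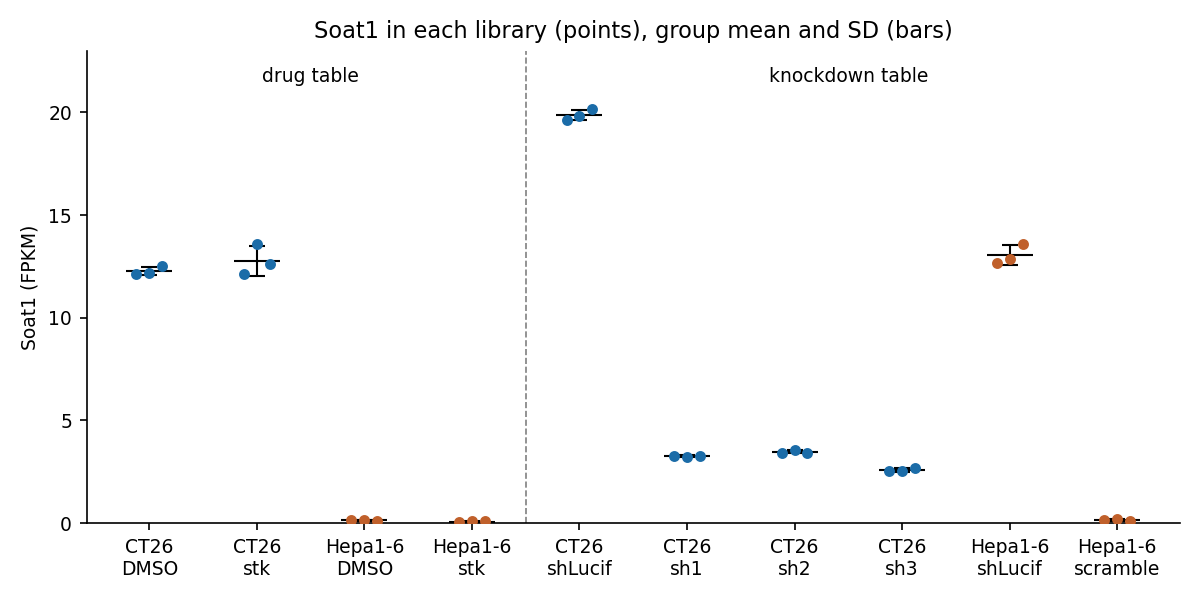
Soat1 in FPKM in each library (points) with the mean and SD of each group of 3 (bars), the drug table on the left and the knockdown table on the right. CT26 hairpin groups lie between 2.59 and 3.47 against 19.9 in their control, and Hepa1-6 shLucif lies at 13.0 while Hepa1-6 scramble lies at 0.146.

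The comparison of stk with DMSO in CT26 asks which genes respond to the drug. Nfix, which encodes a transcription factor of the nuclear factor I family, rose from 3.12 ± 0.135 to 8.82 ± 0.0486 FPKM (ENSMUSG00000001911, chromosome 8, 84699876 to 84800344; log2 fold change 1.25, SE 0.051, adjusted p = 0.00109). Abca1, the membrane pump that exports cholesterol and a target of the oxysterol receptor LXR, fell from 3.95 ± 0.303 to 1.44 ± 0.169 FPKM (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895; -1.02, SE 0.0819, adjusted p = 0.0113). Me1, the malic enzyme that supplies NADPH for fatty acid synthesis, fell from 31.0 ± 0.921 to 20.6 ± 0.564 FPKM (ENSMUSG00000032418, chromosome 9, 86581371 to 86695953; -0.57, SE 0.0405, adjusted p = 0.00845). Ikbkg, a regulator of NF-kB, rose (0.63, adjusted p = 0.019), as did Cdv3 (0.45), Phf13 (0.42), the actin-bundling gene Fscn1 (0.37), Edf1 (0.35), fibronectin (Fn1, 0.33) and glutamine synthetase (Glul, 0.32). The matrix protease gene Adamts1 fell by 0.61 on the log2 scale, Pcmt1 by 0.55 and the RNA polymerase subunit gene Polr2k by 0.50. Several small ribosomal or mitochondrial genes were lower as well, with fold changes of -0.67 in Rpl22l1, -0.48 in Rpl39, -0.41 in Atp5e and -0.40 in Rps21. The pseudogene Rps3a2 (-0.41) and the small RNA Mir6236 (-1.27) share sequence with abundant transcripts, so their values are uncertain.

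In all, 85 of 11358 genes were called by limma in CT26, 15 higher and 70 lower, of which 7 changed at least 2-fold. Protein-coding genes made up 33 of the calls (8 higher, 25 lower) and pseudogenes of any class 43 (5 higher, 38 lower). The share of higher calls was 17.6%, and 30.8% after quantile normalization. With no filter on low values limma called 14 genes, and of 19 named genes with a call 5 kept it (Nfix, Cdv3, Me1, Polr2k and Rps3a2). With a minimum of 5 FPKM it called 133. Among protein-coding genes alone it called 13, and 10 of 17 named genes lost their call, while with the replicate number as a block it called 4, and 17 of 19 lost theirs. It called 43 with the trend with transcript length removed, where 3 of 19 lost theirs, and 204 with all libraries of the table in 1 model. Without DMSO replicate 2 the count was 2 genes, without DMSO replicate 3 it was 9, and without stk replicate 1 it was 12. It was 21 without DMSO replicate 1 or stk replicate 2, and 92 without stk replicate 3. Nfix was called in 6 of these 6 fits, Me1 in 5, Abca1, Cdv3 and Rps3a2 in 4 and Mir6236 in 3. Ikbkg, Rpl22l1, Polr2k, Adamts1, Edf1, Glul, Atp5e, Rpl39 and Rps21 were called in 1 of them, and Fn1, Fscn1, Pcmt1 and Phf13 in 0. In simulated data the test found 9% of genes changed 1.2-fold, 82.1% of those changed 1.5-fold and 97% of those changed 2-fold.

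All 19 measured genes of cholesterol biosynthesis had lower means with stk in CT26 (median log2 fold change -0.28, camera adjusted p = 3.38e-05, and adjusted p = 0.6 with an estimated correlation). No gene of the list passed the test over all genes, and 1 fell when adjusted over the list alone. Among them, Dhcr7 had a fold change of -0.45 (adjusted p = 0.0732), Ebp -0.23 (0.156) and Cyp51 -0.42 (0.255). Fatty acid synthesis genes were lower too (13 of 15, median -0.14, adjusted p = 0.00178, and adjusted p = 0.6 with an estimated correlation), with Me1 called over all genes and 2 genes adjusted over the list alone. Lists shifted upward were DNA replication (19 of 22 genes higher, adjusted p = 0.0015), immediate early genes (11 of 13, 0.0015), immune checkpoint ligands (9 of 11, 0.0212), ATF4 targets (15 of 19, 0.0219), lysosome (16 of 23, 0.0219) and mitochondrially encoded mRNAs (10 of 13, 0.0454). With an estimated correlation none of them passed (adjusted p = 0.457 to 0.74). Their medians were between 0.02 and 0.17, and 0 of their members passed the test over all genes, while 4 mitochondrial mRNAs rose and 1 fell, and 1 ATF4 target rose and 1 fell, adjusted over the list alone.

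The other 18 of the 26 lists tested did not pass. LXR targets (adjusted p = 0.421) held the called fall of Abca1, and adjusted over the list alone 1 member rose and 2 fell. Mesenchymal and matrix genes (0.422) held the rise of Fn1. Interferon-stimulated genes (31 measured, median -0.07) had an adjusted p of 0.859, MHC class I genes 0.752, chemokines 0.34, oxysterol enzymes 0.878, oxysterol receptors 0.336, sterol uptake 0.558, lipid droplets 0.692 and stem cell markers 0.643. The remaining values were 0.0548 for glycolysis, 0.0781 for mitosis, 0.0859 for NRF2 targets, 0.102 for xenobiotic metabolism, 0.717 for ER chaperones, 0.858 for p53 targets, 0.95 for Wnt targets and 0.96 for NF-kB targets. For lipid droplets and MHC class I the median was negative (-0.02 in each) where the test pointed up. Fewer than 3 members were measured for hepatocyte (0), endothelial (0), intestinal (1), leukocyte (2) and fibroblast (2) markers and histones (2).

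In Hepa1-6, the same comparison gave other leading genes. Myadm, a membrane protein gene, rose from 42.2 ± 1.46 to 89.6 ± 2.51 FPKM (chromosome 7, 3289080 to 3300442; 1.07, SE 0.0398, adjusted p = 0.000491), and Cyp1a1, the classic target of the aryl hydrocarbon receptor, from 17.1 ± 1.13 to 29.6 ± 0.966 (chromosome 9, 57687928 to 57703824; 0.76, adjusted p = 0.0107). The complement protease gene C1s1 fell from 38.6 ± 2.49 to 17.1 ± 0.76 FPKM (ENSMUSG00000038521, chromosome 6, 124530345 to 124542359; -1.13, SE 0.0587, adjusted p = 0.00148). Id2, an inhibitor of differentiation, fell from 88.8 ± 1.21 to 56.1 ± 1.46 (chromosome 12, 25093799 to 25097140; -0.65, SE 0.0335, adjusted p = 0.00148). Abca1 fell here as well, from 5.79 ± 0.727 to 3.15 ± 0.357 FPKM (-0.71, SE 0.102, adjusted p = 0.0422). Tgif2 (0.54), Cpne1 (0.53), the heat shock gene Dnajb1 (0.46), Jdp2 (0.44), Ppp1r9b (0.41), Mpp2 (0.40), Pbx2 (0.39) and Pcnx3 (0.39) rose. Metallothionein 2 (Mt2) fell by 0.66, the citrin gene Slc25a13 by 0.61, Ptp4a1 by 0.49 and Zfas1 by 0.45 on the log2 scale. Rpl22l1 (-0.73), Rpl39 (-0.59) and Polr2k (-0.47) were lower, as in CT26.

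There were 175 calls among 11426 genes in Hepa1-6, 78 higher and 97 lower, with 5 changed at least 2-fold. With no filter on low values limma called 4 genes, Myadm, Dnajb1, C1s1 and Id2, so that 24 of 28 named genes lost their call, and with a minimum of 5 FPKM it called 473. With the replicate number as a block it called 4, and 25 of 28 named genes lost their call, while among protein-coding genes alone it called 92, and 3 of 27 lost theirs. It called 53 with the trend with transcript length removed, where 9 of 28 lost theirs, and 928 with all libraries of the table in 1 model. The share of higher calls was 44.6%, and 51.7% after quantile normalization. Protein-coding genes made up 122 of the 175 calls (74 higher, 48 lower) and pseudogenes of any class 45 (2 higher, 43 lower). Leaving out 1 library gave between 8 calls (without DMSO replicate 2 or without stk replicate 2) and 59 (without stk replicate 1). Myadm, C1s1, Id2 and Cyp1a1 were called in 6 of the 6 such fits, Dnajb1 and Rpl22l1 in 4, Rpl39 in 2 and Slc25a13 and Ppp1r9b in 1. Abca1 and the other genes named for this line were called in 0. The test found 23.9%, 74.6% and 92.4% of simulated changes of 1.2-fold, 1.5-fold and 2-fold.

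In this line NF-kB targets were higher with stk (12 of 15 genes, median 0.11, camera adjusted p = 0.00376, and adjusted p = 0.457 with an estimated correlation), with Bcl3 called over all genes (0.36, adjusted p = 0.0265) and 4 genes up adjusted over the list alone. Wnt targets were higher (7 of 8, median 0.14, adjusted p = 0.00605, and adjusted p = 0.524 with an estimated correlation), with a rise of the feedback gene Nkd1 (0.32, adjusted p = 0.0292) and 3 genes adjusted over the list alone. Immediate early genes were higher (10 of 12, adjusted p = 0.0215, and adjusted p = 0.524 with an estimated correlation), with called rises of Jun (0.35) and Fosl1 (0.28). Cholesterol biosynthesis was lower (14 of 20, median -0.13, adjusted p = 0.0215, and adjusted p = 0.6 with an estimated correlation), with a called fall of Msmo1 (-0.40, adjusted p = 0.0409) and 4 genes down adjusted over the list alone. Mitosis genes were lower (16 of 20, adjusted p = 0.0293, and adjusted p = 0.6 with an estimated correlation), with Ccnb1 called (-0.37) and 3 genes adjusted over the list alone. Outside them, Pcna (-0.26) and Csf1 (0.30) were called.

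None of the other 26 lists tested passed in Hepa1-6. Mesenchymal genes had an adjusted p of 0.0811, NRF2 targets 0.122, DNA replication 0.232, xenobiotic metabolism with its called gene Cyp1a1 0.234, ATF4 targets 0.241, intestinal markers 0.245, mitochondrial mRNAs 0.245, oxysterol receptors 0.336 and fatty acid synthesis 0.345. It was 0.426 for MHC class I, oxysterol enzymes and hepatocyte markers, 0.516 for ER chaperones, 0.581 for p53 targets, 0.605 for leukocyte markers, 0.676 for stem cell markers, 0.717 for lysosome, 0.721 for sterol uptake, 0.752 for histones and 0.778 for chemokines. It was 0.858 for LXR targets, 0.859 for lipid droplets and checkpoint ligands, 0.95 for glycolysis and fibroblast markers and 0.958 for interferon-stimulated genes, and only 1 endothelial marker was measured. For LXR targets the mean was negative (-0.02) where the median and the test pointed up.

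The drug responses of both lines were then set against each other. They shared 19 lower genes where 0.63 were expected among 10045 genes tested in both (one-sided Fisher exact test, adjusted p = 6.2e-23), and 1 higher gene, the pseudogene Gm15590 (expected 0.0854, adjusted p = 0.329). Abca1, Rpl22l1, Rpl39 and Polr2k were the protein-coding genes among the 19, and the rest were processed pseudogenes and 1 small RNA. With the trend with transcript length removed, 3 lower genes were shared, Abca1, Rpl22l1 and Rpl39 (0.0641 expected, adjusted p = 9.94e-05), and 0 of them were pseudogenes. Among protein-coding genes alone, 2 were shared, Abca1 and Rpl22l1 (0.0361 expected, adjusted p = 0.00111). No gene was called in opposite directions. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.291 and Spearman's rho 0.249. The difference between the lines itself passed for 39 of 12822 genes (14 higher in CT26 and 25 lower, with 1780 at an unadjusted p under 0.05). Me1 fell in CT26 and not in Hepa1-6, where its fold change was 0.12 (difference -0.69, SE 0.0506, adjusted p = 0.000705), and C1s1 fell in Hepa1-6 and not in CT26 (difference 1.14, SE 0.159, adjusted p = 0.026). The other named genes are Id2 (difference 0.85), the receptor gene Paqr4 (0.56), the NF-kB inhibitor gene Nfkbie (-0.92) and Adamts1 (-0.81). Leaving out single libraries gave between 7 and 28 such genes, and the lowest of these counts came without CT26 stk replicate 1. With the replicate number as a block, 6 such genes were called. Simulated differences of 1.2-fold, 1.5-fold and 2-fold were found in 9%, 70.1% and 83.3% of genes.

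**Figure D2:**
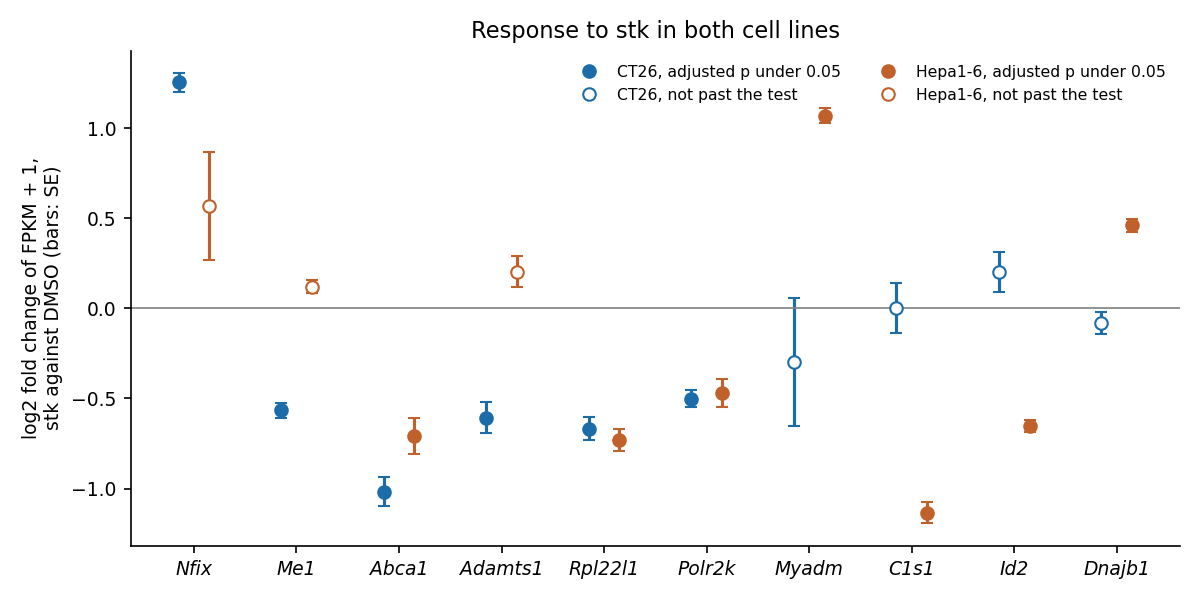
Log2 fold change of FPKM + 1 with its standard error for stk against DMSO in CT26 (blue) and Hepa1-6 (orange), filled where the adjusted p is under 0.05 and open where it is not. Abca1, Rpl22l1 and Polr2k were lower in both lines, Nfix and Me1 passed in CT26 and Myadm, C1s1 and Id2 in Hepa1-6.

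Knockdown of Soat1 in CT26 was compared with shLucif to find genes that follow the loss of the enzyme. Over the mean of the 3 hairpins, the osteoglycin gene Ogn fell from 32.3 ± 1.33 to 6.11 ± 3.21 FPKM (ENSMUSG00000021390, chromosome 13, 49608046 to 49624501; -2.41, SE 0.071, adjusted p = 9.17e-09). The stress hormone gene Fgf21 fell from 7.40 ± 0.633 to 0.836 ± 0.319 (chromosome 7, 45613886 to 45615490; -2.21, adjusted p = 2.25e-07) and the cytokine gene Il11 from 18.3 ± 0.99 to 6.43 ± 1.72 (-1.41, adjusted p = 7.69e-06). Cryab, a small heat shock protein gene, rose from 11.5 ± 0.67 to 38.2 ± 5.87 FPKM (chromosome 9, 50751325 to 50756636; 1.63, SE 0.0518, adjusted p = 9.33e-09), and Cd109, which encodes a TGF-beta co-receptor, from 5.21 ± 0.0715 to 19.1 ± 4.64 (1.66, adjusted p = 1.08e-09). Abca1 rose, from 3.64 ± 0.241 to 6.27 ± 0.631 (0.64, adjusted p = 6.66e-06), the opposite of its direction with stk. The other named genes that rose are Hbb-bh1 (2.09), Qdpr (1.78), Anxa8 (1.59), Dkk2 (1.59), Angptl2 (1.58), Lgals3bp (1.57), Akr1c18 (1.45) and Ntn4 (1.38). Those that fell are Fam107b (-1.98), Aqp8 (-1.92), Cox6a2 (-1.50), Avil (-1.37), Ifi27 (-1.16) and Rpia (-1.08). The SD of the hairpin mean includes differences between hairpins.

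The mean contrast called 5103 of 11832 genes (2764 higher, 2339 lower), of which 73 changed at least 2-fold. The share of higher calls was 54.2%, but 46.8% after quantile normalization and 50.2% after scaling by size factors, so the direction of the majority depends on the scaling. Single hairpins gave 4471 calls with sh1 (2261 higher), 4602 with sh2 (2233 higher) and 6217 with sh3 (3656 higher). With sh3 the share of higher calls was 58.8%, and 47.8% after scaling by size factors. Each of the 3 hairpins called 1727 genes in the same direction, 1029 higher and 698 lower, where 131.8 and 95.8 would be shared if the hairpins were independent and where 0 were called in simulated unchanged groups with a shared control. That expectation counts sh1 and sh2 as separate, although only 2 genes were called between them. It also leaves out that the 3 contrasts share shLucif, so a control group that stands apart gives shared calls too. With the sh3 libraries in the control place, 3264 genes were shared. Neither value can therefore tell an effect of Soat1 loss from other differences between shLucif and the hairpin groups. Between sh1 and sh3, 1198 genes were higher in both and 818 lower in both, against 698.6 and 478.3 expected if independent. Between sh2 and sh3 these were 1167 and 848, against 690 and 512.8. Opposite calls numbered 0 between sh1 and sh2, 882 between sh1 and sh3 and 955 between sh2 and sh3. If independent, 869.8, 1172.3 and 1215.3 would be expected for these 3 pairs. Pearson's r of their fold changes was 0.904, 0.224 and 0.207, against 0.498 in the simulated groups, and their covariance 0.1017, 0.0307 and 0.0288, against 0.0078, so the sh3 pairs lie below the simulated groups by correlation and above them by covariance. Between 50.1% and 61.8% of all genes had no overlap between a hairpin and shLucif, against 10% by chance. Changes of 1.2-fold, 1.5-fold and 2-fold in simulated data were found in 52.2%, 95.5% and 95.5% of genes for the mean, in 34.3%, 89.6% and 98.5% for sh1, in 34.3%, 86.6% and 95.5% for sh2 and in 40.3%, 94% and 95.5% for sh3.

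The hairpins split on interferon. Of 32 interferon-stimulated genes, 30 rose with sh1 (median log2 fold change 1.49, camera adjusted p = 8.4e-25), 31 rose with sh2 (1.62, 1.27e-26) and 31 fell with sh3 (-1.30, 3.09e-20). Isg15, a ubiquitin-like antiviral protein gene, had fold changes of 1.77, 1.84 and -1.91, and Ifit1 of 1.74, 1.95 and -2.15. Usp18, a brake on interferon signalling, stood at 3.53 ± 0.864 FPKM with sh3 and 106 ± 7.31 over sh1 and sh2 (-4.58, adjusted p = 3.72e-11). With an estimated correlation the 3 list tests did not pass (adjusted p = 0.194, 0.179 and 0.262), while these members were called one by one over all genes. Set directly against the mean of sh1 and sh2, sh3 had 7117 called genes and a median of -2.77 for this list (31 of 32 fell, adjusted p = 7.28e-27, and adjusted p = 0.179 with an estimated correlation). The mean over hairpins was positive (27 of 32 rose and 0 fell, 28 rose adjusted over the list alone; median 0.53, adjusted p = 7.06e-10, and adjusted p = 0.524 with an estimated correlation), and it hides the opposite direction of sh3.

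**Figure D3:**
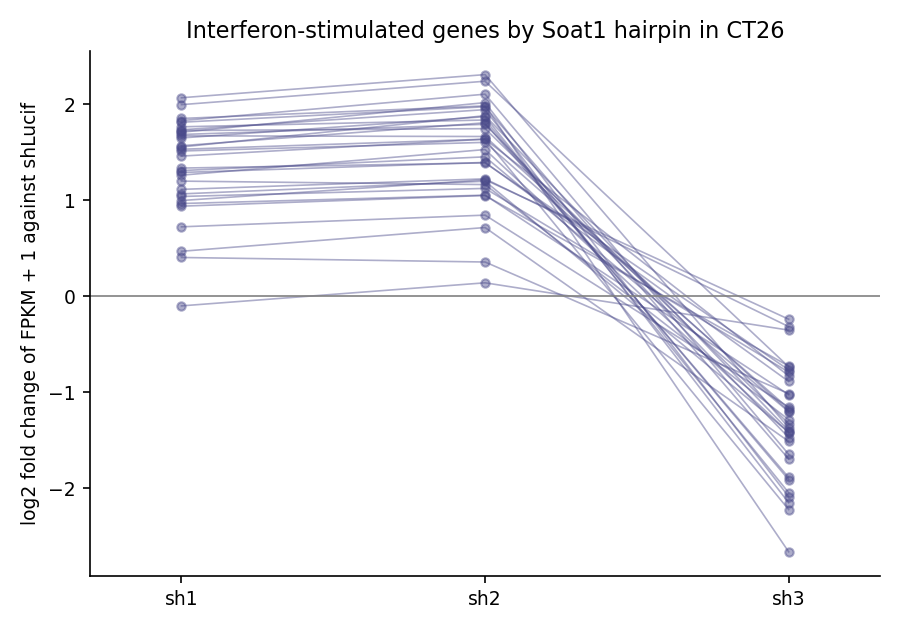
Log2 fold change of FPKM + 1 against shLucif for each of 32 interferon-stimulated genes (lines) with each Soat1 hairpin in CT26. With sh1 the median is 1.49, with sh2 1.62 and with sh3 -1.30.

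Antigen presentation was higher with sh1 and sh2. Of 20 MHC class I genes, 15 rose and 2 fell with sh1 (adjusted p = 5.41e-06, and adjusted p = 0.0365 with an estimated correlation), and 15 rose and 1 fell with sh2 (2.19e-07, and 0.0351 with an estimated correlation). The chaperone gene Tapbp rose from 12.9 ± 0.972 FPKM to 38.2 ± 1.81 with sh1 and 37.7 ± 1.94 with sh2, and H2-D1 from 122 ± 2.28 to 241 ± 3.35 and 249 ± 4.23. With sh3 the list did not pass (adjusted p = 0.774), although H2-D1 rose there too (0.35). Set directly against the mean of sh1 and sh2, 15 of its genes fell and 1 rose with sh3 (median -0.46, adjusted p = 0.000117, and adjusted p = 0.0653 with an estimated correlation). In that contrast 10 lists were called, 3 up and 7 down, and 0 with an estimated correlation. DNA replication genes fell with sh1 (14 of 22, adjusted p = 1.76e-05) and sh2 (17 of 22, adjusted p = 1.16e-05), both with an adjusted p = 0.177 at an estimated correlation. Other lists called with sh1 were lysosome, ER chaperones, checkpoint ligands and histones (higher) and mitochondrially encoded mRNAs (lower), and those with sh2 were lysosome, ER chaperones, histones and checkpoint ligands (higher). With an estimated correlation their adjusted p was 0.282 to 0.624 for sh1 and 0.282 for sh2.

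Besides interferon-stimulated genes, hairpin sh3 moved lists of cholesterol and matrix genes, at the preset correlation only. Of 19 cholesterol biosynthesis genes, 15 rose with sh3 and 2 fell (adjusted p = 0.00252, and adjusted p = 0.368 with an estimated correlation), among them Acat2 (1.34), Nsdhl (1.09), Idi1 (0.94) and Hmgcs1 (0.79). The lipid droplet coat gene Plin2 fell from 116 ± 5.60 to 49.8 ± 4.17 FPKM (-1.2) and Me1 from 22.4 ± 1.21 to 13.4 ± 1.08 (-0.70). Of 18 mesenchymal genes 14 rose (adjusted p = 0.000284), of 20 mitosis genes 15 rose (0.00171) and of 20 ATF4 targets 15 fell (0.000647), with an adjusted p = 0.177, 0.282 and 0.31 at an estimated correlation. Chemokines (7 of 12 fell, 0.0438) and fibroblast markers (4 of 5 rose, 0.0466) passed as well, with an adjusted p = 0.693 and 0.282 at an estimated correlation. The largest changes with sh3 among called genes of at least 5 FPKM whose libraries do not overlap were U90926 (2.74), Hbb-bh1 (2.65), Clca3a1 (2.3), Ogn (-3.47), Avil (-2.94) and Ostn (-2.91). With sh1 they were Gbp2b (2.12), Ifi27l2a (2.08), Gbp3 (2.07), Aqp8 (-2.52), Soat1 and Fgf21 (-2.14), and with sh2 Gbp2b (2.35), Gbp3 (2.31), Gbp2 (2.24), Aqp8 (-2.48), Soat1 and Fam107b (-2.12).

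Besides interferon-stimulated genes, the mean over the hairpins moved 7 lists at the preset correlation. MHC class I genes were higher (15 of 20 rose and 1 fell, adjusted p = 0.000103, and adjusted p = 0.0911 with an estimated correlation). The others had an adjusted p of 0.457 to 0.726 with an estimated correlation. Cholesterol biosynthesis (12 of 19 rose, adjusted p = 0.00776, with Sc5d at 0.58 and Dhcr7 at 0.57), sterol uptake (6 of 12, 0.0179, with Insig1 at 0.61) and mesenchymal genes (12 of 18, 0.00937) were higher. Of the single hairpins, only sh3 had cholesterol biosynthesis and mesenchymal genes called, and sterol uptake was not called with any. DNA replication (14 of 22 fell, 0.000103, with Pola1 at -0.56 and Mcm3 at -0.51), mitochondrially encoded mRNAs (7 of 13, 0.0293) and p53 targets (13 of 18, 0.0403) were lower. None of these falls was called with every hairpin. DNA replication was called with sh1 and sh2 but not with sh3, mitochondrially encoded mRNAs with sh1 alone, and p53 targets with no single hairpin. The immune checkpoint gene Cd274, in a list that did not pass (0.228), rose over the mean (0.70, adjusted p = 5.67e-05), where it rose with sh1 (1.21) and sh2 (1.46) and fell with sh3 (-0.56).

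The other lists did not pass for the mean. LXR targets had an adjusted p of 0.726, fatty acid synthesis 0.847, lipid droplets 0.326, oxysterol enzymes 0.692, oxysterol receptors 0.209, stem cell markers 0.676 (5 of 12 rose and 5 fell), chemokines 0.96, ATF4 targets 0.336, ER chaperones 0.16, mitosis 0.367, glycolysis 0.389 and NRF2 targets 0.422. The values were 0.973 for xenobiotic metabolism, 0.572 for NF-kB targets, 0.752 for Wnt targets, 0.3 for immediate early genes and intestinal markers, 0.0518 for lysosome, 0.0538 for fibroblast markers and 0.0872 for histones. Medians of fatty acid synthesis (0.02) and chemokines (0.12) were positive where the mean and the test pointed down. Hepatocyte (0), endothelial (0) and leukocyte (2) markers had too few measured genes.

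Whether the drug and the knockdown move the same genes was tested on calls in CT26. Among 11179 genes tested in both tables, 4 were higher in both (3.25 expected, one-sided Fisher exact test p = 0.414) and 6 were lower in both (13.9 expected, p = 0.997), with an adjusted p of 1 for each. A further 5 were called in opposite directions. Abca1, Adamts1 and Hist1h4i were lower with stk and higher with the knockdown (16 expected), and Edf1 and Phf13 the reverse (2.82 expected). Genes lower with stk were thus fewer than expected among knockdown calls of either direction, but a deficit was not tested. Pseudogenes made up 38 of the 70 lower calls with stk. The knockdown mean called 230 of 965 pseudogenes, against 43.1% of all genes. These counts therefore cannot tell whether the drug and the knockdown move different genes. Higher in both were Ikbkg, Glul, Fn1 and Gm15590, and lower in both Me1, Rpl22l1, Tmem258, Usp27x and the pseudogenes Gm12854 and Rpl6l. Pearson's r between the fold changes was 0.017 across genes. The cholesterol biosynthesis list was lower with stk and higher with the knockdown mean, a difference that was not itself tested because the experiments are separate tables. Of the single hairpins, only sh3 had this list called, so its rise is not a change common to the hairpins.

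The control hairpins of Hepa1-6 were compared with each other. Because genes that separate CT26 from Hepa1-6 differ between these groups, the comparison cannot be read as a measure of what a control hairpin does. Whether the control hairpin itself made the difference was not tested. The 2 control groups differed more than any other pair of groups inside a line. Alb, the albumin gene, stood at 1.49 ± 0.249 FPKM with shLucif and 135 ± 10.7 with scramble (chromosome 5, 90460897 to 90476602; 5.78, adjusted p = 2.38e-08), and Sprr1a at 36.4 ± 3.68 and 2589 ± 78.5. Tff3 was listed at 0 in the shLucif libraries and at 77.5 ± 3.04 FPKM with scramble. Tmsb4x, an actin-binding thymosin gene that most cells express strongly, was at 194 ± 0.698 FPKM with shLucif and 0.11 ± 0.0464 with scramble (chromosome X, 167207093 to 167209315; -7.46, adjusted p = 1.81e-09). Slc25a4 (150 ± 1.79 and 0.136 ± 0.0424) and Rhox5 (313 ± 16.4 and 2.24 ± 0.682) had the same direction. Soat1 was at 13.0 ± 0.5 FPKM with shLucif and 0.146 ± 0.043 with scramble (-3.62, adjusted p = 3.01e-08), and Soat2 at 1.44 ± 0.0949 and 0.519 ± 0.113.

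Of 12055 genes, 8221 were called between the 2 control groups (3789 higher and 4432 lower with scramble), 1650 of them at least 2-fold, and 73.2% of all genes had no overlap, against 10% by chance. Hepatocyte markers (9 of 9 measured rose with scramble, camera adjusted p = 1.16e-05), intestinal markers (6 of 6, 1.8e-05), cholesterol biosynthesis (16 of 20, 0.000932), fatty acid synthesis (11 of 13, 0.00631), LXR targets (7 of 8, 0.0182), Wnt targets (7 of 8, 0.0182), fibroblast markers (3 of 3, 0.0214) and lysosome (0.0112) were higher with scramble. With an estimated correlation none of them passed (adjusted p = 0.177 to 0.368). Interferon-stimulated genes (27 of 28 fell, 9.47e-09) and ER chaperones (13 of 16 fell, 0.0033) were lower, with an adjusted p = 0.307 and 0.301 at an estimated correlation. The test found 31.3%, 88.1% and 98.5% of simulated changes of 1.2-fold, 1.5-fold and 2-fold. Correlations between libraries over genes were 0.8671 to 0.8717 between these groups and 0.9892 to 0.9911 among the shLucif libraries.

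**Figure D4:**
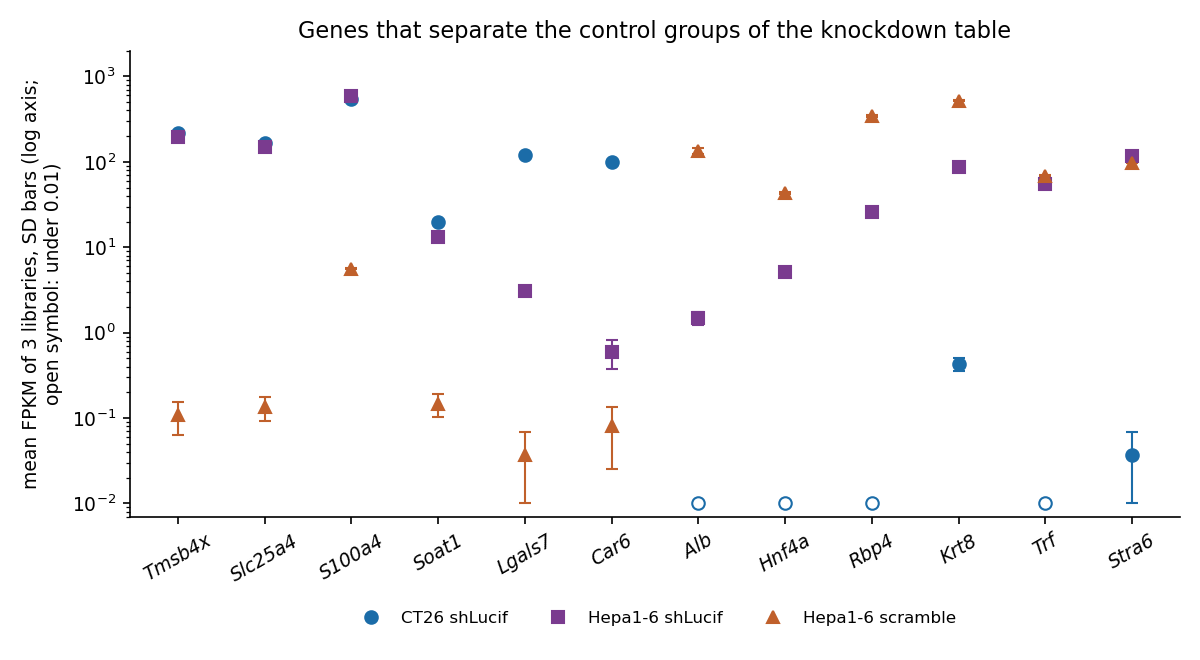
Mean FPKM with SD of 3 libraries for 12 genes in the control groups of the knockdown table, on a log axis, with open symbols at the bottom for values under 0.01. Hepa1-6 shLucif holds Tmsb4x at 194 FPKM, near CT26 shLucif at 217.1, and Trf at 54.8, near Hepa1-6 scramble at 69.2.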

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

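The tests of technical causes in this part, and the contrasts between hairpins, were chosen after the results they address were seen, as were the counts of other groupings for those contrasts; the counts of groupings for the other comparisons were planned.

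The response to stk differed between the lines by a test of the difference itself for 39 genes. Of the 6 named genes among them, C1s1 differed by 1.14 on the log2 scale (CT26 minus Hepa1-6), Id2 by 0.85, Paqr4 by 0.56, Nfkbie by -0.92, Adamts1 by -0.81 and Me1 by -0.69. Only 1 of 100 groupings of the 12 libraries, the real one, gave as many as 39 genes, and the highest other gave 11. Treatment labels were redrawn within each line, which also breaks up any response to stk that the lines share. These groupings therefore cannot tell whether chance gave the difference between the lines. The count itself is not stable, since it fell to 7 without CT26 stk replicate 1 and to 6 with the replicate number as a block. Nfkbie and Paqr4 passed in neither line alone.

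Hairpin sh3 differed from the mean of sh1 and sh2 in 7117 genes, and interferon-stimulated genes differed by a median of -2.77. As many genes were called in 2 of 100 groupings of the 9 libraries. The other grouping, with 7172 genes, also had the 3 sh3 libraries in the sh3 place. A grouping with 3717 genes, the next highest, had all 3 of them in the place of sh2, and no other drawn grouping gave more than 3 genes, so among the drawn groupings high counts came only where the sh3 libraries stayed together. This contrast was chosen because sh3 had been seen to stand apart, so its groupings restate that observation and are no separate test of chance. For the mean over hairpins against shLucif, 2 of 100 groupings of the 12 libraries gave as many as the real 5103 genes, and the highest other, with 5605, had the sh3 libraries in the place of the controls. That same grouping gave 3264 genes shared by 3 hairpins, against the real 1727, which 2 of 100 groupings reached. Among the drawn groupings, both counts were reached only where the 3 libraries of 1 group, shLucif or sh3, filled the control place. These groupings show that CT26 groups differ from each other and that sh3 stands apart. They cannot tell an effect of the hairpins from other differences between the groups, so no conclusion on chance is drawn from them.

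The remaining comparisons have 10 groupings of 6 libraries each, too few for a share under 0.05. The real grouping gave the highest count in each comparison with a control (1 of 10). It was 85 genes against 7 in the highest other for stk in CT26, 175 against 9 for stk in Hepa1-6, 8221 against 1 for scramble, 4471 against 2 for sh1, 4602 against 2 for sh2 and 6217 against 1 for sh3. For sh2 against sh1, 4 of 10 groupings gave at least the real 2 genes, and the highest other gave 3.

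The opposite direction of interferon-stimulated genes with sh3 was weighed against 3 explanations. More residual Soat1 with 1 hairpin would move genes in 1 direction, larger where Soat1 is lower. However, 31 of 32 genes had opposite signs in sh3 and in both others, with Soat1 at 13% to 17.4% of control. Those signs are the pattern itself, so they speak against an effect in 1 direction but are no separate test. For chance values of the shared shLucif libraries, the contrast without them had a median of -2.77. The controls cancel in it, so it restates that sh3 differs from sh1 and sh2. It cannot tell whether chance values placed shLucif between the hairpins, so this explanation is not decided. It also stays open whether the sh1 and sh2 libraries come from 1 population of cells. Only 2 genes (Chchd3, -0.36, and Gm14165, 0.36) were called between them by limma, with 983 at an unadjusted p under 0.05. Their fold changes correlated at 0.904 across genes against 0.498 in simulated unchanged groups. An off-target effect of 1 hairpin, a response to the vector and a true effect of Soat1 loss in part of the lines stay open as well, and none of them was tested.

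The Hepa1-6 shLucif libraries differ from the scramble libraries in genes that separate the 2 cell lines, and hold genes of each. A simple mixture of CT26 and Hepa1-6 cells would hold every marker of a line at 1 share of its level there. However, the ratio of the 90th to the 10th percentile of that share was at least 7.97 over 6 pairs of reference groups. This smallest value came with CT26 DMSO, a group of the separately made drug table, as reference. With references from the knockdown table alone the smallest was 28.3. With CT26 shLucif and scramble as references, 30 CT26 genes had a median of 18% of CT26 (1.59% to 69% between those percentiles) and 38 Hepa1-6 genes a median of 20.7% of scramble (1.62% to 45.9%). CT26 libraries under a Hepa1-6 label are argued against by the same median of 20.7%, where a value near 0 would be needed. Another cell line cannot be told apart from the rest, because only 1 gene (Gm45717, in 1 library alone) was abundant there and absent from both others, and a line related to either would share their genes. Cells of both lines in another state and a hybrid line stay open and were not tested. The control hairpin itself was not tested either. In CT26, group means with the same hairpin correlated at 0.965 with DMSO. Hepa1-6 shLucif correlated at 0.901 with Hepa1-6 DMSO and at 0.917 with CT26 DMSO. These values, from separately made tables, argue against a hairpin effect of this size in both lines. An effect of the hairpin in Hepa1-6 alone stays open. The difference between the control groups therefore cannot be read as a measure of hairpin noise.

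Ribosomal protein genes and pseudogenes, classes that were not among the fixed lists, had lower medians with stk in both lines, although few were called (7 of 87 ribosomal protein genes and 38 of 925 pseudogenes in CT26, 7 of 85 and 43 of 919 in Hepa1-6). A test of the ribosomal protein genes with camera gave an adjusted p = 1.51e-13 in CT26 and 1.56e-16 in Hepa1-6, and an adjusted p = 0.304 in each with an estimated correlation. For pseudogenes these were 6.79e-09 and 2.71e-12, and an adjusted p = 0.176 in each with an estimated correlation. A library preparation that lost short transcripts would lower other short genes as well, and protein-coding genes under 800 bases outside the ribosomal families had a median of -0.091 in CT26 (186 genes) and -0.144 in Hepa1-6 (193 genes), against 0.008 and 0.033 in genes of at least 3000 bases. Reads shared with parent genes would lower both alike, and ribosomal protein genes had a median of -0.092 in CT26 (73 of 87 lower) and -0.141 in Hepa1-6 (77 of 85 lower), next to -0.093 and -0.13 in pseudogenes. Transcript length was that of the longest annotated transcript of each gene, which can be longer than the transcript expressed. Removal of the trend with that length can therefore leave part of a length effect behind. After the removal, lower calls among pseudogenes went from 38 to 8 and from 43 to 8, and their medians to -0.003 and -0.012. Ribosomal protein genes kept more of their shift, with medians of -0.043 (25th to 75th percentile -0.118 to 0.031) and -0.085 (-0.214 to -0.007), with 3 and 2 called lower, and with a camera adjusted p = 1.26e-05 and 4.22e-09, and adjusted p = 0.383 and 0.304 with an estimated correlation. Both technical explanations predict values like those of the pseudogenes, so the shared lower pseudogenes may be no response of the cells. Over all protein-coding genes, Spearman's rho between fold change and transcript length was 0.133 in CT26 and 0.223 in Hepa1-6. In Hepa1-6, 56 of the 74 protein-coding genes called higher had at least 3000 bases. Among genes tested in both lines, higher calls went from 66 to 19 in Hepa1-6 and from 13 to 17 in CT26 with the trend removed. The fixed lists were not tested with it removed, so length may bear on other results as well. For the ribosomal protein genes a part of the shift was left once the length trend was removed, by the test at the preset correlation only, so whether length explains all of it stays open, and a smaller output of ribosomal genes with stk, untested, stays open.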

How the results depend on the processing

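Tests on protein-coding genes only, with the length trend removed, of gene classes, and with other weightings of the hairpins were chosen after the results were seen; the others were planned.

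Counts for stk depended on the settings. With no filter on low values limma called 14 genes in CT26 and 4 in Hepa1-6, and with a minimum of 5 FPKM 133 and 473. Named genes lost their call in 14 of 19 cases in CT26 and 24 of 28 in Hepa1-6 with no filter, in 17 of 19 and 25 of 28 with the replicate block in 10 of 17 and 3 of 27 with protein-coding genes only, in 3 of 19 and 9 of 28 with the length trend removed and in 2 of 19 and 4 of 28 with 1 model per table. With the replicate number as a block it called 4 and 4, and 6 in the difference between lines. With all libraries of the table in 1 model it called 204 and 928, with protein-coding genes only 13 and 92, and with the length trend removed 43 and 53. The filters and the gene class change how many and which genes share the adjustment and the variance trend, a block takes up degrees of freedom, and the joint model adds them; beyond that the cause was not tested. Leaving out 1 library gave 2 (without DMSO replicate 2) to 92 (without stk replicate 3) genes in CT26, 8 (without DMSO replicate 2 or stk replicate 2) to 59 (without stk replicate 1) in Hepa1-6 and 7 (without CT26 stk replicate 1) to 28 (without Hepa1-6 stk replicate 2) for the difference. These omissions gave fewer genes in every fit but 1, and why single libraries matter this much was not tested.

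With an estimated correlation 0, 0 and 0 lists were called by camera for stk in CT26, stk in Hepa1-6 and the hairpin mean, against 8, 5 and 8; estimated correlations (0.721 for cholesterol biosynthesis in CT26) exceed the preset 0.01. Lower genes shared by the lines with stk went from 19 to 3 with the length trend removed and to 2 among protein-coding genes. Asking for a 2-fold change in both left 0 of 10 genes in the overlap of stk and the knockdown. Hist1h2ae, a histone gene, changed sign in the hairpin mean when sh1 and sh3 alone were averaged (-0.0151); the cause was not tested.

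Counts of the hairpin comparisons, shared hairpin calls and scramble stayed within 1.5 times under all settings run, and Soat1 kept its fall. Leaving out libraries gave 4122 to 5157 genes for the mean, 3720 to 4503 for sh1, 3775 to 4716 for sh2, 5396 to 6315 for sh3, 1364 to 1637 for the shared calls and 7030 to 7242 for scramble. For named genes, 3482 values under other settings kept direction and side of the threshold, 126 lost and 77 gained a call and 1 changed sign. With 1 library left out 2957 kept both, 227 lost and 8 gained a call. No replicate block was run for sh1, the mean and the shared calls, because the numbers of the sh1 columns do not single out a replicate. Libraries of the same replicate number had residual correlations of at most 0.095. In the drug experiment these exceeded the highest value with another number for numbers 2 and 3 in each line, but not for number 1. No test of pairing was run, so whether the numbers pair the libraries stays open. The Hepa1-6 hairpin settings were not run. Unknown read totals limit what can be said of genes at low FPKM.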

Other observations

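No hypothesis in this part was tested; the values were looked at after the main results were seen.

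Mitochondrial transcripts took a share of all FPKM that differed between the CT26 groups of the knockdown table. The share was 11.3% ± 0.22 (SD, n = 3) with shLucif, 9.44% ± 0.96 with sh1, 10.1% ± 0.15 with sh2 and 11.2% ± 0.43 with sh3. In the drug table it was 12.5% ± 0.05 with DMSO and 13.0% ± 0.15 with stk in CT26. No test was run on these shares.

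The group means of Hepa1-6 shLucif correlated over 13562 genes with CT26 DMSO at 0.917, with Hepa1-6 DMSO at 0.901 and with both scramble and CT26 shLucif at 0.897, while scramble and Hepa1-6 DMSO correlated at 0.985 and scramble and CT26 shLucif at 0.752. These values set separately made tables side by side. Of 187 genes with at least 10 FPKM in scramble and under 0.2 in CT26 shLucif, 152 reached 1 FPKM in Hepa1-6 shLucif, and of 148 genes with the reverse pattern 125 did.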
